A study of Mus musculus with 8 samples.

How the data were processed

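H3K4me3 ChIP-seq was made from testes of adult C57BL/6 mice that were wild type or null for H3f3b. The series has 8 samples, of which 4 are H3K4me3 libraries (2 per genotype) and 4 are input libraries. A region list was examined for each H3K4me3 library. Input libraries were not analysed here. Libraries are named by the genotype and the number in their labels (WT 66, WT 74, KO 67 and KO 73). Nothing in the labels states that each number is a separate animal. The p-values of values per library and of limma therefore measure only the spread between these libraries, which may be technical. Tests on counts of regions take regions as the units, and their p-values do not measure that spread.

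Bowtie and HOMER are named, and mm9 is given as the genome build, per the submitters' processing notes. Their versions and settings, any filters, and whether the inputs entered the calling are not given in the sources used here. The deposited lists are BED tables with 1 list per library, so the regions were called per library and not on pooled reads. Each region has a chromosome, a start, an end and a score that the authors' tool gave it, and the deposited score has no stated scale. Its values were found to be whole multiples of 1 step per library, within rounding to 1 decimal. The step was 0.874 in WT 66, 1.39 in WT 74, 0.325 in KO 67 and 1.45 in KO 73. All scores below 100 lay within 0.055 of such a multiple, where chance gives from 7.59% to 33.8%. A tag count times a constant would give such a grid. If a step is 1 tag and all lists were scaled to the same total, which is not stated, a finer step means a deeper library. On that reading, the depth relative to the shallowest library was 1.66, 1.04, 4.46 and 1 in the same order. The smallest score in each list was 20.1, 20.9, 20.2 and 20.3, which stood for 23, 15, 62 and 14 tags. The absolute depth is unknown. The score was used only to rank and filter regions within a list. The narrowest region was 501 bp in every list. Positions were checked against the build: from 66 to 96 regions per list lay beyond the last gene of their chromosome in the GRCm38 gene table that was at hand, which is another build, so none of its coordinates was used.

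Scaffolds without a chromosome and the mitochondrial genome were left out. Starts were converted to count from 1. Regions of the 4 libraries were merged where they overlapped or touched, and a library covered a union region if it overlapped it by at least 1 bp. A lost region was covered in both WT and neither KO library, and a gained region in both KO and neither WT library. Values per library were compared by 2-sided exact permutation tests over the 6 labelled splits of the 4 libraries, in which the smallest p is 0.33. Overlap was the Jaccard index in base pairs, given for the 3 divisions of the libraries into pairs. Covered lengths of regions found in all 4 libraries were tested as log2 values, without a pseudocount, with limma (lmFit and eBayes with a variance trend) at a Benjamini-Hochberg adjusted p of 0.05. Shares of regions have 95% exact (Clopper-Pearson) intervals, which cover counting error only, and were compared with Fisher's exact test, 2-sided. Expected losses came from regions of like WT score: both-WT regions were put in 20 bins of their WT score rank, and the share lost in each bin was taken as the chance of loss of its regions, with 1-sided exact Poisson-binomial p-values that treat regions as independent.

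The tests, the rule for named regions and the alternatives were fixed before the data were examined, except for those said here or below to be later. Named regions were the 5 lost and the 5 gained union regions with the largest value of the smaller covered length among the libraries that held them, the 5 most narrowed and the 5 most widened shared regions past an adjusted p of 0.05 or, where fewer passed, with both KO values beyond both WT values, and the 3 widest regions of each library. Counts on single autosomes, expected losses from score, bins of width, windows along chromosomes and the number of regions of at least 3000 bp were added later. Promoter counts and tests of germ cell, somatic cell and chromatin gene lists had been planned only for the case that gene positions in mm9 were at hand. They were not run, and the targeted gene itself was not examined.

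The limma step was tested on simulated widths of 9742 regions. It called 85 of 100 regions changed by 1 on the log2 scale, 100 of 100 changed by 2, and 27 of 9542 unchanged ones, so that 12.7% of its calls were false, above the 5% aimed at. The simulated widths had no floor at 501 bp and no region left the shared set, so these rates need not hold for narrowing in the data. A first simulation took each region's sample variance as its true spread and gave no calls, so the variances were then drawn towards their common value. The alternatives were a stricter score threshold (regions below the 25th percentile of a list dropped), lists cut to the length of the shortest, a minimum width of 1000 bp, autosomes only, joining of regions within 1000 bp, coverage of at least 50% of a union region, regions found in at least 2 libraries with 100 bp added before the log, other scalings of width, limma without a variance trend, and leaving out each library. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.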

Results

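H3K4me3, the trimethylation of lysine 4 of histone H3 that marks active promoters, was mapped by ChIP-seq in whole testes of adult C57BL/6 mice. The mice were either wild type for H3f3b (WT) or H3f3b null (KO). H3f3b is a gene for H3.3, the histone H3 variant that is put into chromatin outside DNA replication. Each genotype had 2 H3K4me3 libraries, WT 66 and WT 74 against KO 67 and KO 73, and a list of enriched regions was examined for each. The 4 input libraries of the series had no list here and were not analysed. The question put by the design was where and how far H3K4me3 regions of the testis differed without H3f3b. Regions are given by their mm9 coordinates, because no gene positions in that build were used here.

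Testes without H3f3b had fewer and shorter H3K4me3 regions, and the number of broad ones fell by a larger share than that of all regions. The lists held 14078 regions in WT 66, 14551 in WT 74, 10502 in KO 67 and 12497 in KO 73. The mean was 14314.5 ± 334 regions in WT and 11499.5 ± 1411 in KO (SD, n = 2 each), 19.7% lower in KO. The regions covered 21.6 ± 0.573 Mb in WT and 15.3 ± 1.15 Mb in KO, 29.3% less. Regions of at least 3000 bp numbered 960 and 835 in the WT libraries and 162 and 221 in the KO libraries, a mean of 897.5 ± 88.4 against 191.5 ± 41.7 (SD, n = 2). They made up 6.28% ± 0.764 of a WT list and 1.66% ± 0.160 of a KO list. A region that narrows past 3000 bp leaves this count without being missing. Of the both-WT regions of at least 3000 bp, 8.94% (by width in WT 66) and 11.1% (WT 74) were absent from a KO library. Among those below 1000 bp the shares were 52.3% and 47.7%. Median region width overlapped between the genotypes, at 1390 and 1272 bp in WT and 1294 and 1187 bp in KO.

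For the number of regions, the covered length and the number of broad regions, both KO libraries lay below both WT libraries, with p = 0.33 in each 2-sided exact permutation test. That is the smallest p this design allows, so none of these differences could reach significance. The exact p for median width was 0.667, and its KO minus WT difference of -90.5 bp ran from -149.5 bp without WT 74 to -31.5 bp without WT 66 and was -318 bp, with exact p = 0.33, in lists of one length. The lists did not order by sequencing depth as read from the steps of the deposited scores: relative to KO 73, the depth was 1.04 in WT 74, 1.66 in WT 66 and 4.46 in KO 67, which had the fewest regions.

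**Figure D1:**
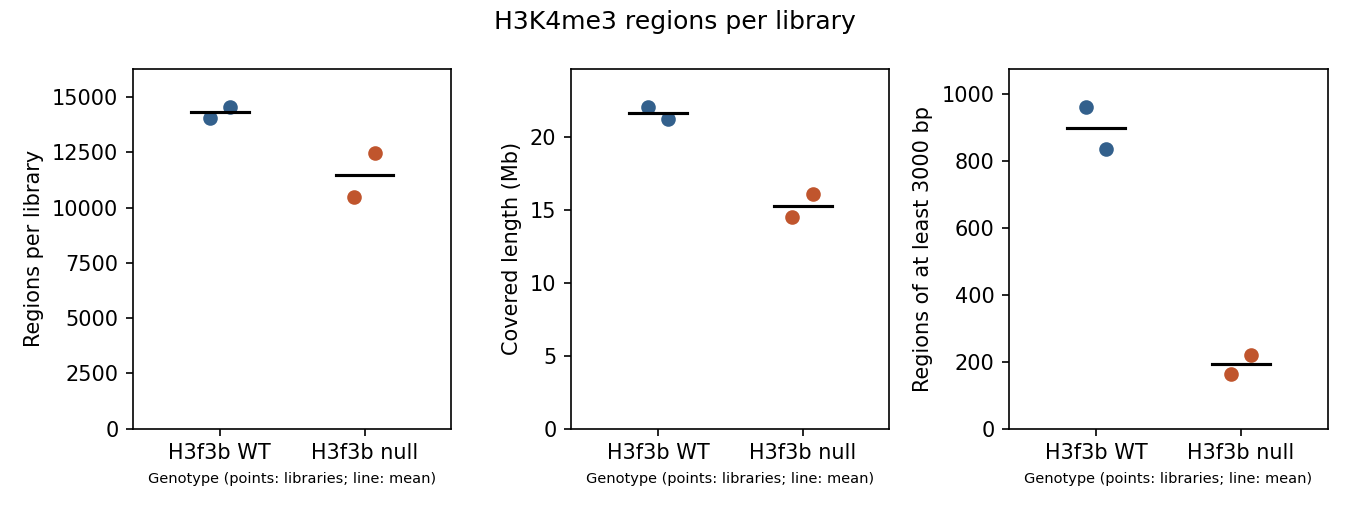
Number of H3K4me3 regions, covered length in Mb and number of regions of at least 3000 bp in each library, by genotype (points, libraries; black lines, means of 2 libraries). Both H3f3b null libraries lay below both WT libraries in each panel, with 162 and 221 broad regions against 960 and 835.

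The widest domains of the WT testes were shorter in both KO libraries. The widest region, on chromosome 16 from 17890329 to 17902102, spanned 11774 bp in WT 66 and 11261 bp in WT 74, and 2812 bp of it was covered in KO 67 and 5522 bp in KO 73. A domain on chromosome 9 from 107448883 to 107458397 measured 9515 and 9222 bp in WT and 4372 and 6096 bp in KO. On chromosome 13 from 23399164 to 23408080, WT coverage of 8917 and 8621 bp stood against 2285 and 3844 bp in KO. The widest region of KO 67 itself, on chromosome 17 from 71197989 to 71203842 (5854 bp), lay in a domain of 6839 and 6728 bp in the WT libraries. The widest of KO 73, on chromosome 10 from 127528240 to 127535192 (6953 bp), lay in one of 8193 and 8189 bp. The regions were picked for their width in 1 library, which by itself favours a smaller width in the others, and single regions were not tested here.

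Libraries of one genotype had a higher Jaccard index with each other than libraries of different genotypes. The Jaccard index, the shared length over the joint length, was 0.718 between the WT libraries and 0.713 between the KO libraries, and from 0.605 to 0.619 between a WT and a KO library. The mean within genotypes exceeded the mean between genotypes by 0.103. The index falls where 2 libraries differ in covered length, here 22.0 and 21.2 Mb in WT against 14.5 and 16.1 Mb in KO. The gap therefore does not show that a KO library shared a larger part of its regions with the other KO library than with WT. In the other 2 ways of dividing the 4 libraries into pairs the difference was -0.0498 and -0.0529. With 3 divisions, no exact p below 0.33 was possible.

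Regions lost in the null testes outnumbered regions gained, by a margin that went with the length of the lists. Merging the 4 lists gave 16519 union regions, of which 9742 were found in all 4 libraries. Of the 12560 regions present in both WT libraries, 1485 were absent from both KO libraries, 11.8% (95% exact binomial interval 11.3 to 12.4), and are called lost. Of the 10015 regions present in both KO libraries, 59 were absent from both WT libraries, 0.589% (0.449 to 0.759), and are called gained. A further 1333 regions of both WT libraries were found in 1 KO library. With each list held to the length of the shortest, 613 regions were lost and 497 gained.

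The lost regions that ranked first by the smaller of their WT covered lengths were broad. The first, on chromosome 2 from 25142034 to 25147989, covered 5342 bp in WT 66 and 5742 bp in WT 74 and had no region in either KO library. A region on chromosome 13 from 56525593 to 56530859 covered 4050 and 4478 bp in WT, and 2 on chromosome 16 covered 3886 and 3997 bp (34649001 to 34653014) and 3777 and 3965 bp (10789243 to 10793931). The last of the 5, on chromosome 3 from 146310336 to 146314992, covered 4657 and 3726 bp. Most lost regions were weak and short. Their median rank by the authors' score was the 20.7th percentile of the WT 66 list and the 25th of the WT 74 list, against 64.1 and 64.8 for regions found in all 4 libraries. Their median covered length was 849 and 851 bp in the WT libraries, against 1647.5 and 1528 bp. The share lost fell from 49.5% in the lowest of 20 bins of WT score rank to 0 of 628 regions in the highest.

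The gained regions were small. The first by the smaller of its KO covered lengths, on chromosome 2 from 169458791 to 169460055, covered 1195 bp in KO 67 and 1265 bp in KO 73. The next were on chromosome 4 from 100964789 to 100966239 (1122 and 1451 bp), chromosome 1 from 173001914 to 173003107 (1154 and 1080 bp), chromosome 13 from 74945311 to 74946339 (941 and 902 bp) and chromosome 17 from 35974182 to 35975360 (836 and 1179 bp). The 59 gained regions had a median covered length of 626 bp in KO 67 and 753 bp in KO 73 and a median score rank at the 5.43rd and 19.7th percentiles of those lists.

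The other divisions of the libraries into pairs gave 43 and 306 regions exclusive to a pair, and 241 and 25, so the 1485 lost regions exceeded each of these, while the 59 gained regions did not exceed the 306 and 241. The number lost was 2897 without WT 66, 2474 without WT 74 and 2576 without KO 73, and the number gained was 185 without WT 66, 147 without WT 74, 693 without KO 67 and 95 without KO 73.

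**Figure D2:**
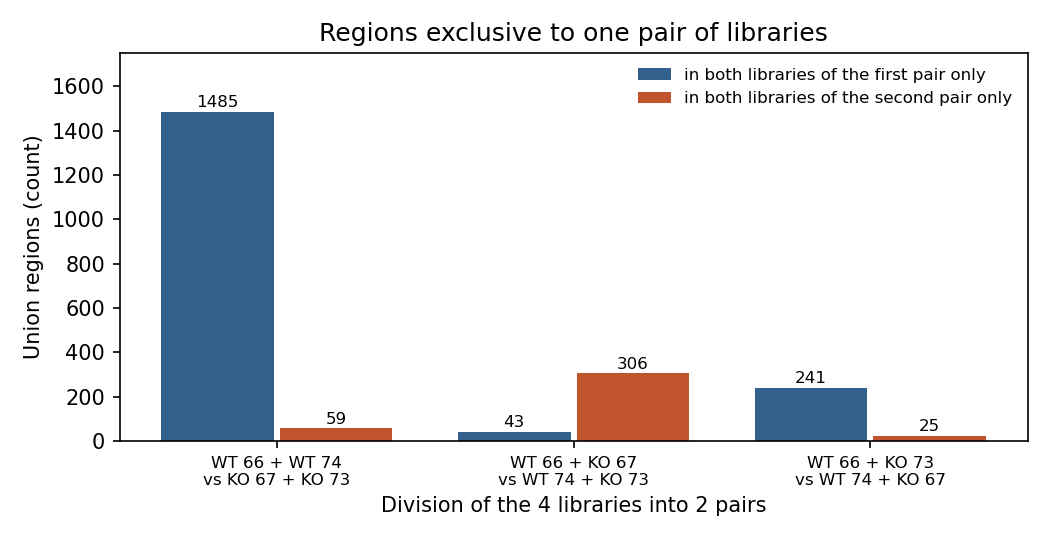
Union regions found in both libraries of 1 pair and in neither library of the other pair, for the 3 ways of dividing the 4 libraries into pairs (bars, number of regions). Division by genotype gave 1485 WT-only and 59 KO-only regions, and no bar of the other divisions exceeded 306.

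Where H3K4me3 regions were present in all 4 libraries, most were narrower in the null testes, and the wide ones narrowed most. Among the 9742 shared regions the median covered length was 1647.5 bp in WT 66, 1528 bp in WT 74, 1344 bp in KO 67 and 1354 bp in KO 73. The median log2 change was -0.18, and 80.1% of the regions had a lower mean log2 length in KO. Both KO values lay below both WT values in 4618 regions (47.4%) and above them in 462 (4.74%), where a random order of 4 values gives 16.7% each way. All regions share the same 4 libraries, so a shift of a whole library moves many of them together and this rate is no test. Counted either way, the genotypes were separated in 5080 regions, and the pairs of the other 2 divisions in 2516 and 2083. By limma with Benjamini-Hochberg adjustment over the 9742 regions, 352 regions changed in width, 351 of them narrower and 1 wider.

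The 352 regions were wide in WT, with a median covered length of 3121.5 bp that was 1381.5 bp in KO, against 1588.5 and 1348.5 bp over all shared regions. This follows in part from how they were picked, since only a region wide in WT can fall far and still reach 501 bp. The region with the largest fall, on chromosome 13 from 59831399 to 59836482, covered 4936 ± 209 bp in WT and 564.5 ± 89.8 bp in KO (SD, n = 2), and its log2 change was -3.14 ± 0.16 (SE; limma adjusted p = 0.0109). A region on chromosome 7 from 39311362 to 39315215 fell from 3420 and 3649 bp to 501 bp in each KO library (log2 change -2.82, limma adjusted p = 0.0109), and 501 bp was the narrowest region in any list. On chromosome 5 from 135474854 to 135478420, coverage fell from 3302 and 3065 bp to 501 bp in each KO library (log2 change -2.67, limma adjusted p = 0.0141). In these regions of chromosomes 7 and 5 the narrowest width fixed both KO values. Their lack of spread in KO is therefore no measure of agreement, and their adjusted p may be too small. On chromosome 11 from 78006195 to 78010095, coverage fell from 3623 and 3330 bp to 501 and 636 bp (log2 change -2.62, limma adjusted p = 0.0160). The last of the 5 most narrowed, on chromosome 19 from 10073339 to 10078691, covered 3305 and 5353 bp in WT and 501 and 943 bp in KO (limma adjusted p = 0.0339, and from 0.0598 to 0.0679 without a variance trend, with either scaling of widths, or with regions of at least 2 libraries). All 5 regions had a KO value of 501 bp, that of KO 73 on chromosome 13 and of KO 67 on chromosomes 11 and 19. The narrowest width therefore limited the size of these falls. Their KO scores, from 20.3 to 37.7, lay near the smallest scores of the KO lists (20.2 and 20.3), so these regions were close to not being called in KO.

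The 1 region that widened was on chromosome 17 from 86565787 to 86568053, with 1029 and 960 bp in WT and 2090 and 2267 bp in KO (log2 change 1.13 ± 0.14 SE, limma adjusted p = 0.0259). Among regions that did not pass the test but whose KO values both exceeded both WT values, the largest log2 changes were 0.97 on chromosome 7 from 119822088 to 119823947 and 0.95 on chromosome 6 from 108162506 to 108163894. Those on chromosome 10 from 59569053 to 59570484 and chromosome 17 from 53828111 to 53829525 had log2 changes of 0.95 and 0.94. The limma adjusted p of these 4 ranged from 0.0723 on chromosome 7 to 0.162 on chromosome 6.

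Among regions of at least 1000 bp, the change grew with the WT width when regions were binned in 1 WT library and the KO mean was set against the other. Binned by WT 66, the median log2 change was -0.11 from 1000 to below 2000 bp, -0.19 from 2000 to below 3000 bp, -0.43 from 3000 to below 5000 bp and -0.84 in the 86 regions of 5000 bp or more. Binned by WT 74, it ran from -0.21 to -0.84 over the same bins. With regions absent from a KO library counted as the largest falls, the medians over these bins ran from -0.17 to -0.89 and from -0.26 to -0.90. Shorter regions could not be compared in this way, because a region near the floor of 501 bp leaves the shared set instead of narrowing. Of the both-WT regions below 1000 bp, 52.3% (WT 66) and 47.7% (WT 74) were absent from a KO library. With these counted as the largest falls, the median was -0.87 binned by WT 74 and lay among the absent regions binned by WT 66. On that count the change did not grow steadily with width from the shortest regions.

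With any 1 of WT 66, WT 74, KO 67 or KO 73 left out, a genotype has a single library, and limma then called 0 regions, with 1095 to 1736 at an unadjusted p under 0.05, while the log2 changes of the 5 most narrowed regions ran from -3.30 to -2.16. Subtracting library medians moved the median log2 change to 0.05 and left 80 calls (79 narrower), quantile normalization left 56 (54 narrower), and limma without a variance trend left 98 (97 narrower).

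**Figure D3:**
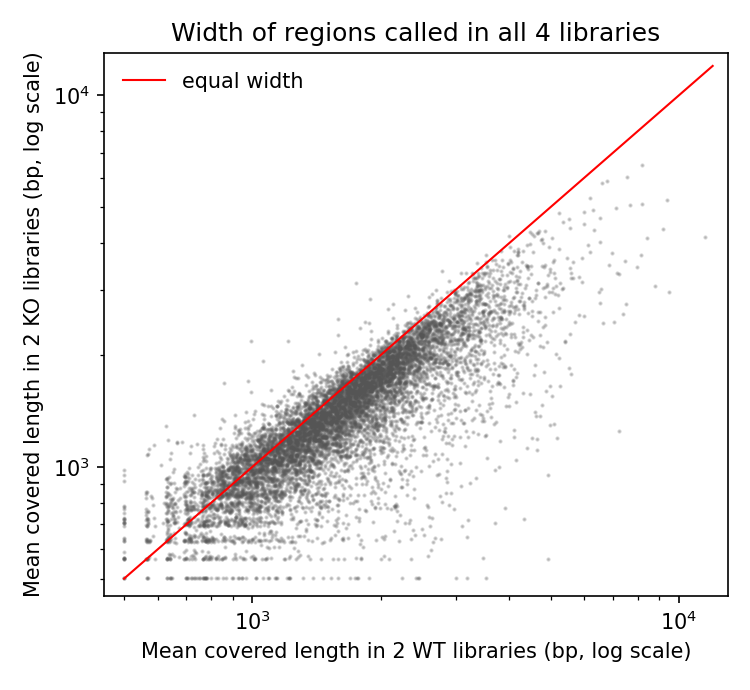
Mean covered length in the 2 KO libraries against that in the 2 WT libraries for the 9742 regions found in all 4 libraries (points, regions; both axes in bp on a log scale; red line, equal width). Most points lie below the line, with both KO values below both WT values in 4618 regions, and the gap widens towards long regions.

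H3K4me3 regions on the sex chromosomes, which are silenced during male meiosis, took shares of the lists that overlapped between the genotypes. The X chromosome held 2.74% ± 0.0742 of the regions of a WT list and 2.60% ± 0.278 of a KO list (SD, n = 2; exact permutation p = 0.667), and the Y chromosome 0.0805% ± 0.0167 and 0.0709% ± 0.0210 (exact permutation p = 0.667). Of the regions present in both WT libraries, 56 of 325 were lost on X, 17.2% (13.3 to 21.8), against 11.7% on autosomes (Fisher's exact test, adjusted p = 0.0103 over 8 tests). Taken over all union regions, the lost share was 11.1% on X and 8.91% on autosomes and did not pass (adjusted p = 0.109, Fisher's exact test). Gained regions numbered 7 on X, 2.97% (1.2 to 6.02) of the X regions of both KO libraries, against 0.522% on autosomes (Fisher's exact test, adjusted p = 0.00320). On Y, 3 of 9 regions were lost and 1 of 7 gained, with adjusted p of 0.104 and 0.0733 by Fisher's exact test. In a comparison added after these counts had been seen, regions of like WT score gave 78.3 expected losses on X, more than the 56 observed (1-sided exact test, adjusted p = 0.0102 over 21 chromosomes). These tests treat regions as independent, which neighbouring regions are not. No comparison by score was made for the gained regions. X regions were also missing more often between libraries of the same genotype. Of WT 66 regions, 13.8% on X and 9.92% elsewhere were missing from WT 74 (19.95% and 12.5% the other way). Of KO 67 regions, 5.98% and 3.27% were missing from KO 73 (32.2% and 18.1% the other way). These shares on X were from 0.648 to 0.869 times those expected from score. The larger gained share on X need not reflect genotype.

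Loss was uneven between autosomes, in a count over chromosomes that was added after the lists had been seen. The tests of these counts treat regions as independent, which neighbouring regions are not, and do not measure the spread between libraries. On chromosome 14, 143 of 558 regions of both WT libraries were lost, 25.6% (22.1 to 29.5), against 11.2% elsewhere (Fisher's exact test, adjusted p = 5.71e-19 over 21 chromosomes). Chromosome 5 followed with 143 of 894, 16% (adjusted p = 0.00136). The share was lower than elsewhere on chromosomes 2, 11 and 19, at 9.03%, 8.57% and 7.14% (adjusted p = 0.0187, 0.00627 and 0.0117). Against the losses expected from regions of like WT score, the number lost was 1.96 times as high on chromosome 14 and 1.43 times on chromosome 5 (1-sided exact tests, adjusted p = 4.52e-18 and 5.85e-06). It was 0.623 times the expected number on chromosome 19 (adjusted p = 0.0102), and the 0.806 on chromosome 2 and 0.847 on chromosome 11 did not pass (adjusted p = 0.0641 and 0.140, 1-sided exact tests). Within 9 Mb of the start of chromosome 14, WT 66 and WT 74 held 67 and 68 regions, and KO 67 and KO 73 held 6 and 21. Between 41 and 45 Mb the numbers were 66 and 61 in WT and 11 and 22 in KO. No rule set the bounds of these stretches, which were chosen after the lists had been seen, so their counts are a description and no test.

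**Figure D4:**
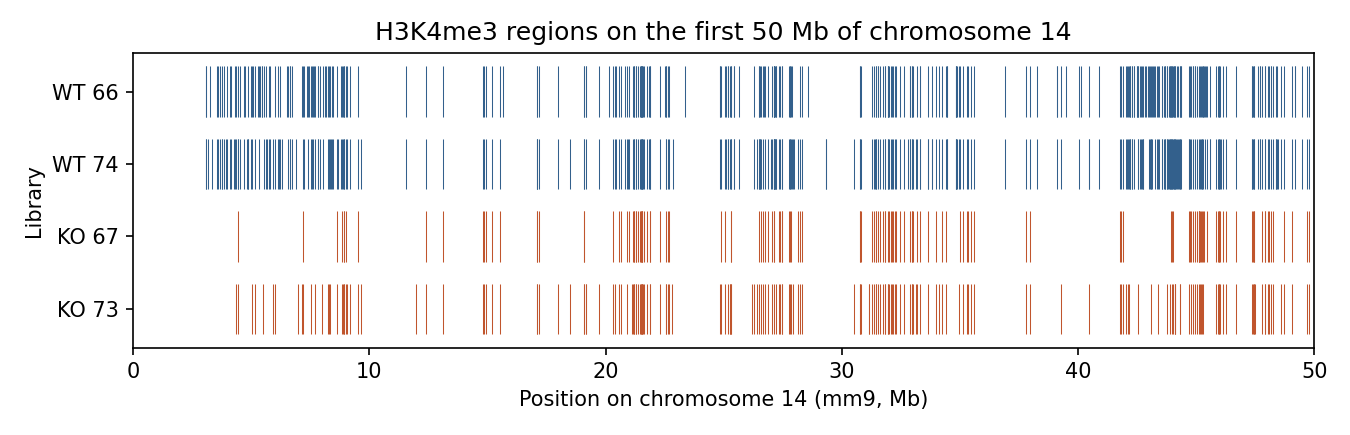
Positions of H3K4me3 regions over the first 50 Mb of chromosome 14 (mm9, in Mb) in each library (vertical marks, regions). The first 9 Mb held 67 and 68 regions in the WT libraries and 6 and 21 in the KO libraries, and the stretch from 41 to 45 Mb held 66 and 61 against 11 and 22. The bounds of both stretches were chosen after the lists had been seen.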

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

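Some alternatives were chosen after the data had been seen. These kept only WT 74 and KO 73, the libraries of like depth, or left out a library for the overlap. All those for regions of at least 3000 bp were later too. Region number, covered length, median width, broad regions and overlap within genotypes kept their direction under every alternative run. The fall in regions ran from -3812.5 without KO 73 to -1817.5 without KO 67. That in median width ran from -318 bp (lists of one length) to -31.5 bp (without WT 66). Leaving out libraries could not turn regions, covered length or broad regions, where both KO libraries lay below both WT. The stricter threshold, lists of one length and minimum width left the difference in broad regions at -706, so did not test it. In this design, no exact p of these measures could fall under 0.33. The KO minus WT difference in the share of regions on X turned from -0.148 percentage points to 0.486 with lists cut to one length and ran from -0.345 to 0.0481 when a library was left out. That on Y turned from -0.00968 to 0.00657 with the stricter score threshold, 0.0381 with lists of one length, 0.00549 with the minimum width and 0.00116 as a share of covered length, and ran from -0.0245 to 0.00516 when a library was left out, so neither chromosome had a direction. Lost regions numbered 613 with lists of one length, from 1727 to 2897 with a library left out, and 3164 between WT 74 and KO 73, where a region has fewer libraries to pass. Gained regions numbered 20 with the stricter threshold, 497 with lists of one length, from 95 to 693 with a library left out, and 1060 between WT 74 and KO 73. Changed widths numbered 98 without a variance trend, 80 with library medians subtracted, 56 with quantile normalization, 101 at 50% coverage, 1872 in regions of at least 2 libraries with 100 bp added, and 0 whichever library was left out, where 1 genotype has a single library that is assumed to vary like the other. Of the 352 calls, 98, 80 and 55 were also made by the first 3 of these. The causes were not tested. Over the 20 named lost, gained, narrowed and widened regions, none of the 203 values that could be had changed direction. This was largely fixed by how the regions were picked. Lost and gained regions were absent from both libraries of a genotype, so that only joining could have turned them. Leaving out a library could not turn narrowed or widened regions, whose KO values both lay beyond both WT values. Of the values of lost or gained regions, 7 moved. Of the 10 narrowed or widened ones, none had a value at 50% coverage or with the minimum width, 1 had one with the stricter threshold and 3 with lists of one length, since the others were then no longer shared. Their calls ended in 28 values, 24 of them with a library left out, where no region passed and the narrowed ones kept log2 changes from -3.30 to -2.16. The other 4 were of the narrowed region on chromosome 19.

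No paired analysis was possible because the genotypes share no library number, and the inputs that share numbers with the H3K4me3 libraries had no list here. Lists of one length give no difference in regions per library by construction. Promoter windows and gene lists were not run, for want of gene positions in mm9.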

Other observations

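The patterns weighed here were seen in the data first. The bound on losses among the strongest regions was set after the patterns but before its values were seen. So were the tests of shuffled windows, of a single shift of widths and of repeat calling on chromosome 14. The tests of depth, immunoprecipitation, a single KO library, score on chromosome 14 and cell composition were chosen after. So were the Fisher tests of the strongest regions, the bins with absent regions and the single regions and windows.

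The region with the highest score in WT 66, WT 74 and KO 67 was the same one, on chromosome Y from 2856634 to 2858572 as listed in WT 66, with 1939, 1683, 1454 and 879 bp covered in WT 66, WT 74, KO 67 and KO 73. In KO 73 the highest score, 53.1 times the median of that list, belonged instead to a region of 501 bp on chromosome 9 from 3022964 to 3023464 that no other library had. Among the 2747 regions in the top 25% of both WT lists by score, 4 were lost. They were the named regions on chromosomes 2, 13 and 3 and a short one on chromosome 19 from 61275411 to 61276304, with 752 and 894 bp in the WT libraries.

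Of 995 windows of 1 Mb with at least 5 regions of both WT libraries, 4 had lost at least 80% of them: chromosome 5 from 127 to 128 Mb (5 of 6 regions lost), chromosome 14 from 3 to 4 Mb and from 6 to 7 Mb (6 of 6 each) and chromosome 16 from 89 to 90 Mb (4 of 5). Against regions of like WT score, 4 windows had an excess of losses at an adjusted p under 0.05 over 995 windows. These lay on chromosome 5 from 11 to 12 Mb (9 of 14 lost, 1.51 expected) and on chromosome 14 from 6 to 7 Mb (6 of 6, 1.21 expected), 42 to 43 Mb (11 of 15, 3.16 expected) and 43 to 44 Mb (15 of 21, 3.78 expected). Together they held 67 and 65 regions in WT 66 and WT 74, and 2 and 16 in KO 67 and KO 73.

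The null libraries had fewer and narrower regions. A difference in depth between the genotypes is argued against, provided that all scores were scaled to the same total. By the score steps, KO 67 was then the deepest library (4.46 times KO 73) and KO 73 the shallowest, close to WT 74 at 1.04. Both KO libraries lay below both WT libraries in regions, covered length and broad regions. The smallest scores of the lists were alike, from 20.1 to 20.9, so the length of a list need not follow depth. Weak regions slipping under the calling threshold may account for most losses, since the share lost fell from 49.5% in the lowest to 0 in the highest of 20 bins of WT score rank and 94.0% of lost regions lay in the lower 50%. The losses among the top 25% of both WT lists, 4 of 2747 or 0.146% (0.0397 to 0.372), passed the bound set in advance, the 0.0287% (1 of 3485) of the top 25% of WT 66 missing from WT 74 (0 of 3571 in the other direction; Fisher's exact p = 0.177, 0.0357 and 0.0239 against the first, the other and both), but that bound was wrong by design, since WT lists of like enrichment do not show what lower enrichment would do at each rank, and the explanation stays open for these 4. Whether a weakening came from less efficient immunoprecipitation, from less H3K4me3 or from a changed cell composition of the null testes cannot be told apart. Covered length in KO was 70.7% of WT, and the lists carry no common scale of H3K4me3 level.

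Regions found in all 4 libraries were narrower in KO. A single shift of all widths in a library is argued against, since after centring each comparison the change in regions of at least 3000 bp minus that in regions from 1000 to below 2000 bp was -0.344 on the log2 scale when binned by WT 74 and -0.349 when binned by WT 66, with the library used for binning kept out, and the same bins kept their order when absent regions were counted as the largest falls (-0.17 against -0.52 binned by WT 66, -0.26 against -0.62 binned by WT 74). A gradual thinning at the edges of wide domains, from lower enrichment or from the loss of H3f3b, might give this and was not tested. A changed cell composition of the null testes was not tested either.

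Lost regions gathered on chromosome 14 and in single windows. A low score of the regions is argued against by 1000 shuffles of the losses among regions of like WT score. They gave at most 2 windows of 1 Mb that had lost at least 80%, against 4 observed (permutation p = 0.0010, the smallest they can give). At 500 kb they gave at most 4 windows against 8. At 2 Mb the margin was thinner, since 2 shuffles reached the 3 observed (permutation p = 0.0030). Chromosome 14 also lost 1.96 times the number expected from score. A fault of 1 KO library is argued against too: windows chosen by KO 67 alone lacked 48.2% of both-WT regions in KO 73 (38.8 to 57.8), against 13.4% in other windows, and windows chosen by KO 73 lacked 96.4% in KO 67 (87.7 to 99.6), against 20.2%. Less repeatable calling on chromosome 14 stays open. Regions of WT 66 were missing from WT 74 there at 1.18 times the expected number (adjusted p = 0.477, exact), against 1.39 and 1.57 times in KO 67 and KO 73. Those of WT 74 were missing from WT 66 at 1.05 times (adjusted p = 0.917, exact), against 1.29 and 1.44 times. The gap of over 20% set in advance was thus reached for KO 73 in both directions but not for KO 67. Between the KO libraries, regions of KO 67 on chromosome 14 were missing from KO 73 at 1.62 times the expected number (22 of 376, adjusted p = 0.257, exact). Those of KO 73 were missing from KO 67 at 1.11 times (adjusted p = 0.404, exact). A changed cell composition of the null testes, reads shared between near-identical copies and an effect of H3.3 on these stretches cannot be told apart without annotation of the coordinates, and 111 of the 516 chromosome 14 regions outside the 4 windows with an excess were lost as well, 21.5% against 11.1% on other chromosomes.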
